A study of Mus musculus with 2 samples.

How the data were processed

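Spatial gene expression was measured on cryosections of snap-frozen wild-type mouse conceptuses, with the placenta as the named tissue, in 1 section at embryonic day 10.5 (E10.5) and 1 section at embryonic day 12.5 (E12.5). In this kind of assay a tissue section lies on an array of barcoded capture spots, and each spot reports the transcripts of a small region that can hold several cells of different types. The only groups the labels give are the 2 stages, so n = 1 per stage, no replicate check exists, and no p-value or standard error was computed.

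For each section the authors deposited a matrix of unique molecular identifier (UMI) counts per gene and spot, which Space Ranger 1.3.1 wrote per the file headers. The submitters' processing notes name Space Ranger, Seurat and the mouse build mm10, without saying which step each served. The extraction text in the labels instead describes bulk RNA from cells and SMART-Seq libraries, which goes against spot matrices; the chemistry of the spot libraries is not given in the sources used here, and that the values are UMI counts rests on the Space Ranger header. The gene annotation used for counting, and how reads matching several genes were handled, are not given in the sources used here. Values of multigene families with near-identical members (prolactins, Psg, Ceacam, cathepsins, globins and granzymes) are therefore uncertain between the members of a family. The counts were used as deposited, with no normalization by the authors. The matrices held 342 spots at E10.5 and 714 at E12.5, the same numbers that the deposited slide alignments mark as lying over tissue, of 4992 spots on each capture area. Spots were analysed without their places on the section.

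The authors also deposited a table of cluster marker genes for each section. Per the file headers it gives a p-value and an adjusted p-value, an average log2 fold change, and the fraction of spots with the gene inside and outside each cluster. The authors' deposited tables were described as they stand, and their clusters were numbered as in the files. No table assigning the spots to those clusters was used here.

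UMIs were summed over all spots of a section and expressed as CPM, the count of a gene scaled to a common total per section or region class. Each CPM has an exact 95% Poisson interval, and each E12.5 to E10.5 ratio an exact conditional binomial (Clopper-Pearson) 95% interval. These intervals cover counting error only, and not the differences between conceptuses, planes of cutting or library preparations. A gene was called higher or lower at a ratio of at least 2 either way, with an interval that excluded 1 and at least 20 UMIs in the 2 sections together. Folds against a count of 0 were computed against a floor of 3 UMIs per section or region class (0.200 CPM in the E10.5 section and 0.135 CPM in the E12.5 section) and written as "at least". The floor is about the one-sided 95% limit for a count of 0, and lies below the upper end of the 95% Poisson interval. Chromosome positions were taken from the GENCODE M21 annotation of mm10 by Ensembl gene identifier, which held 32158 of the 32285 identifiers in the matrices. Of the rows, 78 share a symbol with another gene and were kept apart by identifier.

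Gene lists for cell types (junctional zone, trophoblast giant cell, labyrinth trophoblast, decidual stroma, uterine natural killer, myeloid, primitive and definitive erythroid, endothelium, fetal mesenchyme, yolk sac endoderm, smooth muscle, uterine epithelium and embryo proper) and for function or quality (glycogen metabolism, steroidogenesis, nutrient transport, angiogenic signalling, cell cycle, hypoxia and glycolysis, imprinted, extracellular matrix, interferon response, complement and coagulation, trophoblast transcription factors, immediate early, mitochondrially encoded, Y-linked, Xist and prolactin family) were fixed before the data were examined, together with the comparisons, the rules for named genes and most alternatives. For each list the median log2 ratio of the measured members was placed among 10000 random lists of the same size, matched on mean CPM in 20 bins. Its percentile describes these 2 libraries. A percentile bootstrap over the members of a list gave a 95% interval of its median, which describes the spread of the members. Lists share members, so their results are not independent.

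Named genes followed a fixed rule. For the whole section they were the 12 highest and 12 lowest ratios by the interval bound nearest to 1, among genes with at least 100 CPM in the higher section and without haemoglobin, mitochondrial and predicted Gm genes. Within a region class they were the 6 highest and the 6 lowest by the same rule. From each list they were the pair with the highest mean CPM and the members with the highest and the lowest ratio. Other genes are named only where a sentence says that they were chosen after their values were seen.

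Regions were found in each section on its own with scanpy 1.11.5 and igraph 0.11.9. Spots with at least 200 genes were scaled to 10000 counts, transformed as ln(x+1), and reduced to 2000 variable genes and 20 principal components. A graph of 15 neighbours was then divided by the Leiden method at resolution 0.8. Regions are named by number and by their 5 leading genes by fold, among genes with at least 50 UMIs in the region. A region belonged to a class when that class's list had the most members, and at least 3, among the region's top 30 genes. A class was compared between sections only where no region of it had more markers of another class in its top 10. Labyrinth trophoblast (E10.5 region 7, E12.5 regions 5 and 8) and smooth muscle (E10.5 region 5, E12.5 region 3) met this rule. No doublet caller and no deconvolution were used.

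Alternatives were scaling by the TMM factors of edgeR 4.0.16, by the size factors of DESeq2 1.42.0 or by totals without haemoglobin and mitochondrial genes; equal weight for each spot; a minimum of 1000 UMIs per spot; and thinning of each spot to 2000 UMIs. The minimum UMIs per gene (none, or 100), the fold limit (1.5), the clustering resolution (0.4 and 1.2), 10 principal components, variable genes without haemoglobin, mitochondrial and ribosomal protein genes, clustering of both sections together, and classes from the top 20 genes were varied as well. After the data had been seen, the comparison was also run without E12.5 region 12, and without that region and the smooth muscle regions of both sections.

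The steps were tested on simulated data, drawn for the whole-section comparison from the real means and library sizes with 50 genes at each of 4 ratios. The rule called 0% of genes at a true ratio of 1.5, 100% at 3 and at 4, and 98% at 0.3333. It called 0.373% of 14485 unchanged genes, and the 95% intervals held the true ratio for 95.5% of 14685 genes. Of 200 random lists without a difference, 3.5% lay outside the central 95% of the matched lists. Clustering of 240 simulated spots found 4 of 4 regions, with an adjusted Rand index of 0.989. Both simulated sections came from the E10.5 proportions with counting error alone. The random lists held genes picked independently, and the simulated spots came from 4 E12.5 region profiles. These tests therefore check the steps only. They give no support to the calls, percentiles or region classes of the real sections. Other tools were R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.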

Results

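The data were UMI counts per gene in capture spots over cryosections of whole wild-type mouse conceptuses, 1 section at E10.5 with 342 spots and 1 section at E12.5 with 714 spots. The E10.5 section held 14983134 UMIs and the E12.5 section 22216950. The median spot held 36869 UMIs and 6523.5 genes at E10.5 (5516 to 159046 UMIs per spot) and 28028.5 UMIs and 5770.5 genes at E12.5 (472 to 123829 UMIs). At least 1 UMI was found for 18967 genes at E10.5 and for 20180 at E12.5. Haemoglobin genes made up 2.84% of the UMIs at E10.5 and 3.15% at E12.5, ribosomal protein genes 13.7% and 14.1%, and mitochondrially encoded genes 7.69% and 3.92%. With 1 section per stage, each difference below is a difference between these 2 sections, without a replicate check, and intervals in parentheses are 95% intervals of counting error.

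The series compares placenta between the 2 stages, and the whole sections were compared first. By the fixed rule, the 12 highest E12.5 to E10.5 ratios were those of Ceacam14, Prl7a2, Ceacam11, Ceacam13, Cts3, Psg27, Ceacam5, Tpbpb, Trem2, Guca2b, Akr1b7 and Prap1, and Rnase2a, Tdo2 and the decidual Prl8a2 were among the 12 lowest. Ceacam14 (ENSMUSG00000023185, chromosome 7, 17812633 to 17815663 in mm10), a carcinoembryonic antigen family member expressed in trophoblast, was at 0.334 CPM at E10.5 and 185 CPM at E12.5, 553-fold higher (237 to 1705). Prl7a2 (ENSMUSG00000046899, chromosome 13, 27658584 to 27668036), a placental prolactin-family hormone, was 323-fold higher (199 to 566), from 1.07 to 345 CPM. Rnase2a (ENSMUSG00000047222, chromosome 14, 51255262 to 51256112), a secreted ribonuclease, was at 435 CPM at E10.5 and 11.7 CPM at E12.5, 37.0-fold lower (32.7 to 42.0). Prl8a2 (ENSMUSG00000018259, chromosome 13, 27345673 to 27354216), the decidual prolactin-related protein, was 3.88-fold lower (3.85 to 3.92), from 11777 to 3032 CPM.

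Ceacam11 was 258-fold and Ceacam13 234-fold higher in the E12.5 section, and Ceacam5 was 73.2-fold higher. Cts3, a placental cathepsin, was 168-fold higher, and Psg27, a pregnancy-specific glycoprotein, 97.4-fold. Tpbpb, a relative of the spongiotrophoblast marker Tpbpa, was at 13.1 CPM at E10.5 and 464 CPM at E12.5, 35.3-fold higher (30.6 to 40.8). Trem2, a receptor of myeloid cells, was 37.3-fold higher (27.4 to 52.1), from 2.74 to 102 CPM. Guca2b, which encodes the peptide uroguanylin, was 23.4-fold higher (22.0 to 24.8). Prap1, a secreted protein of uterine and gut epithelium, was 21.4-fold higher (20.7 to 22.1), from 239 to 5105 CPM, and the aldo-keto reductase Akr1b7 was 26.7-fold higher (21.6 to 33.5). Without the 30 spots of E12.5 region 12, described below, these ratios were 9.19 for Guca2b, 8.32 for Prap1 and 12.4 for Akr1b7. With each spot weighted equally, the ratio was 296 for Ceacam14, 124 for Ceacam11, 122 for Ceacam13, 84.1 for Cts3 and 20.7 for Tpbpb. After each spot was thinned to 2000 UMIs, it was 112 for Prl7a2, 36.8 for Cts3, 45.9 for Ceacam5, 79.3 for Trem2 and 51.4 for Akr1b7. Thinning left 684000 UMIs in the E10.5 section, where these genes had only 14 to 86 UMIs before thinning. These thinned ratios therefore rest on few E10.5 UMIs and are imprecise. No interval was computed for thinned ratios, here and below.

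Among the lowest ratios, Tdo2, a tryptophan-degrading enzyme of decidua, was at 373 CPM at E10.5 and 37.0 CPM at E12.5, 10.1-fold lower (9.37 to 10.9). A2m, the protease inhibitor alpha-2-macroglobulin, was 3.82-fold lower (3.78 to 3.85), from 12217 to 3200 CPM. The chemokine Cxcl14 was 4.52-fold lower (4.4 to 4.65), and Gja1, the gap junction protein connexin 43, was 3.99-fold lower (3.87 to 4.12). Prl3d1, placental lactogen I of giant cells, was 4.61-fold lower (4.23 to 5.03), from 142 to 30.7 CPM, and Prl7a1 was 3.88-fold lower (3.77 to 4.0). Nccrp1 was 6.69-fold lower, Krtdap 4.08-fold (2.66-fold without region 12 and the smooth muscle regions of both sections), Ramp3 3.71-fold and Nampt 3.68-fold. With each spot weighted equally, Cxcl14 had a ratio of 0.352, against 0.221 from the summed UMIs, and after thinning Nccrp1 had a ratio of 0.243.

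Of 14987 genes with enough UMIs, 1479 were at least 2-fold higher in the E12.5 section and 569 at least 2-fold lower. The median log2 ratio of all these genes was 0.10, and TMM scaling moved it by -0.095. Of the 29 lists with more than 1 member, 14 had a median above the central 95% of their matched random lists and 8 a median below it. The bootstrap interval over the members included 0 for some of these lists, namely giant cell, prolactin family, definitive erythroid, fetal mesenchyme, steroidogenesis, nutrient transport, angiogenic signalling, imprinted, complement and coagulation, and trophoblast transcription factors.

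**Figure D1:**
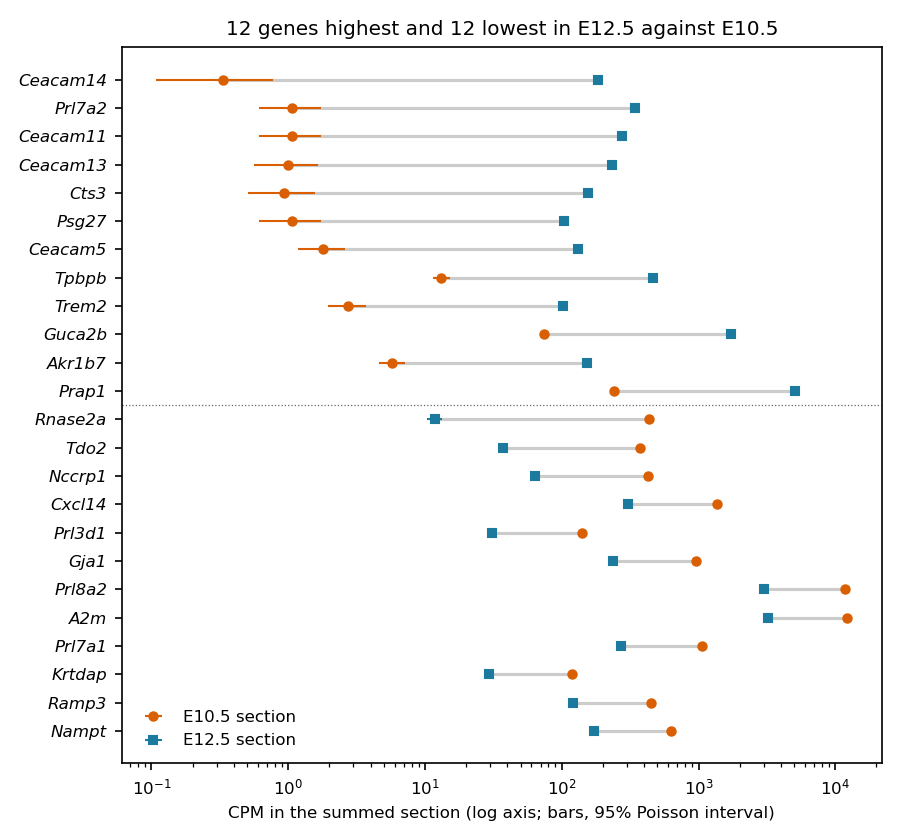
CPM in the summed E10.5 and E12.5 sections, on a log axis, for the 12 genes with the highest and the 12 with the lowest ratio by the fixed rule. Each point is a gene in 1 section, with the 95% Poisson interval of its CPM as a bar. Ceacam14 had the highest ratio, 553, and Rnase2a the lowest, at 37.0-fold lower.

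Trophoblast lists had medians above the matched random lists. Of 30 measured junctional zone genes, 22 were higher in the E12.5 section and 0 were lower (median log2 ratio 2.98, percentile 100). Tpbpa (ENSMUSG00000033834, chromosome 13, 60938492 to 60941984), the classical spongiotrophoblast marker, was 11.3-fold higher (11 to 11.5), from 494 to 5554 CPM, and Prl2b1 was 2.68-fold higher. Tpbpa had a ratio of 7.05 with equal weight per spot, and Prl8a1 a ratio of 0.674 (0.403 to 1.13). The giant cell list went both ways, with 14 of 28 genes higher and 7 lower (median 0.95, percentile 100). Its summed level was 28929 CPM at E10.5 and 27334 CPM at E12.5, against the sign of the median. Most of that sum was Ctla2a alone, at 23635 and 18479 CPM (ratio 0.782). Ctla2a was highest in E10.5 region 5 and E12.5 region 1, outside the giant cell regions. Lower members of the giant cell list included Prl3d1 and Prl3d3, which was 7.60-fold lower, while Prl3b1, placental lactogen II, had a ratio of 1.85. The 24 measured prolactin-family genes were likewise divided, 11 higher and 7 lower (median 0.71, bootstrap interval -0.92 to 1.70, percentile 100). Their summed level was lower at E12.5, 11143 CPM against 16385 CPM, of which the decidual Prl8a2 alone was 3032 CPM against 11777 CPM. Of 33 labyrinth trophoblast genes, 12 were higher and 2 lower (median 0.75, percentile 100). The uncharacterised transcript 1600012P17Rik was 10.2-fold higher (6.66-fold with equal weight per spot), from 10.3 to 105 CPM, Peg10 had a ratio of 1.43, and Igfbpl1 was 7.91-fold lower. At E10.5, 45.8% of the 96 Igfbpl1 UMIs were in region 4, led by neural progenitor genes. 1600012P17Rik was highest in E10.5 region 2 and E12.5 region 4. Neither ratio therefore stands for labyrinth tissue alone. Trophoblast transcription factors had 4 of 33 higher and 2 lower (median 0.26, percentile 98.0). Among them Pparg, a nuclear receptor needed for the labyrinth, was 2.58-fold higher and Sox2 5.47-fold lower, with 49.2% of the Sox2 UMIs at E10.5 in region 4, which was led by neural progenitor genes, while Cited1 and Cited2 had ratios of 1.65 and 1.27. The percentile of the transcription factor list was 87.9 with equal weight per spot and 58.6 after thinning.

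Natural killer, myeloid, smooth muscle and uterine epithelium lists also lay above their matched random lists. Of 20 uterine natural killer genes, 19 were higher and 0 lower (median 2.55, percentile 100). The granzymes Gzmd and Gzmf, the cytotoxic proteases of these cells, were 7.97-fold (7.78 to 8.16) and 7.59-fold higher, Gzmd from 486 to 3870 CPM, and the receptor gene Klrk1 was 10.1-fold higher (3.75 to 38.3). Ncr1 had a ratio of 1.93, and of 3.65 without region 12 and the smooth muscle regions of both sections. Klrk1 had a ratio of 20.4 in that setting and of 6.56 with equal weight per spot. Of 18 myeloid genes 7 were higher and 0 lower (median 0.87, percentile 100). Tyrobp, the adaptor protein through which Trem2 signals, was 3.93-fold higher, from 37.9 to 149 CPM, and Cd14 had a ratio of 0.539. At E12.5, 41.9% of the Tyrobp UMIs were in region 1, of the uterine natural killer class, while Trem2 was highest in region 7. All 13 smooth muscle genes were higher (median 3.05, percentile 100), with Actg2, the enteric smooth muscle actin, 11.7-fold higher (11.1 to 12.2) and Acta2 8.80-fold. Without region 12 and the smooth muscle regions of both sections, Actg2 had a ratio of 5.98 and Acta2 one of 4.50. Of 13 uterine epithelium genes 9 were higher and 0 lower (median 1.59, percentile 100). Sprr2f, an oestrogen-responsive uterine epithelial gene, was 70.4-fold higher (34.0 to 176), Krt7 had a ratio of 1.58 and Foxa2 of 0.820. Without region 12, which held 52.0% of the Sprr2f UMIs at E12.5, the ratio of Sprr2f was 35.9. Foxa2 had 56.7% of its UMIs in E10.5 region 6 and 60.2% in E12.5 region 9, of the yolk sac class. Krt7 was highest in labyrinth regions, E10.5 region 7 and E12.5 region 8. The list therefore does not stand for uterine epithelium alone.

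Decidual, endothelial and steroidogenic lists lay below their matched random lists. Of 32 decidual stroma genes 11 were lower and 3 higher (median -0.51, percentile 0). Mt4 was 7.35-fold lower and the relaxin receptor gene Rxfp1 was 3.41-fold higher. Rxfp1 had a ratio of 1.41 without region 12 and the smooth muscle regions. Of 22 endothelial genes 4 were lower and 0 higher (median -0.64, percentile 0). In the labyrinth class compared below, 2 of 21 were higher and 0 lower (median 0.44, percentile 99.6). In the smooth muscle class 4 of 22 were higher and 4 lower (median -0.22, percentile 4.66). Vwf, von Willebrand factor, was 3.58-fold lower, from 61.7 to 17.2 CPM, while Fabp4, Cdh5 and Apln had ratios of 1.10, 0.756 and 1.81. With equal weight per spot Vwf had a ratio of 0.436. Of 16 steroidogenesis genes 5 were lower and 3 higher (median -0.47, percentile 0). Cyp11a1, the side-chain cleavage enzyme that makes pregnenolone, was 3.37-fold lower (3.23 to 3.52), from 459 to 136 CPM. Akr1c18, which inactivates progesterone, was 2.71-fold lower (4.46-fold without region 12 and the smooth muscle regions) and Star, the cholesterol carrier of the same pathway, 3.59-fold lower. Cyp17a1 was 2.28-fold higher, and 1.89-fold with equal weight per spot. Of 30 angiogenic signalling genes 5 were lower and 2 higher (median -0.28, percentile 0). Flt1, which encodes a receptor for vascular endothelial growth factor, was 5.66-fold higher (5.09 to 6.31), from 25.4 to 144 CPM. Angpt2 was 2.07-fold lower, and 1.96-fold without region 12. Calcrl, the adrenomedullin receptor gene, was 3.0-fold lower, and 1.47-fold after thinning. Epas1 had a ratio of 0.581.

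Blood and embryonic lists were mixed. Of the 3 measured primitive erythroid globins, Hbb-bh1 was 2.37-fold lower, from 3382 to 1429 CPM, while Hbb-y and Hba-x had ratios of 1.37 and 0.922 (list median -0.12, percentile 21.1). Of 15 definitive erythroid genes 1 was higher and 0 lower (median -0.26, percentile 0.47), and the higher gene was the adult globin Hbb-bt, at 445 CPM at E10.5 and 1213 CPM at E12.5, 2.73-fold higher. The other adult globins had ratios of 0.994 for Hbb-bs, 1.22 for Hba-a1 and 0.694 for Hba-a2. The summed definitive erythroid level was 10060 CPM at E10.5 and 11833 CPM at E12.5, against the sign of the median. The definitive erythroid percentile was 2.52 without region 12 and the smooth muscle regions. Of 20 fetal mesenchyme genes 7 were higher and 1 lower (median 0.49, percentile 99.9). Hoxd13, a posterior homeobox gene, was 7.64-fold higher (2.40 to 38.9), Hand2os1 3.29-fold lower, and the collagen genes Col1a1 and Col1a2 had ratios of 1.10 and 1.22. Col1a1 was highest in the smooth muscle regions, with 38.1% of its UMIs in E10.5 region 5 and 36.1% in E12.5 region 3. Region 1 held 49.0% of the Hand2os1 UMIs at E10.5. The list therefore does not stand for fetal mesenchyme alone. Hand2os1 was 1.86-fold lower after thinning. Of 29 yolk sac endoderm genes 2 were higher and 0 lower (median 0.08, percentile 56.8). Afp, alpha-fetoprotein, had a ratio of 1.43, from 11328 to 16162 CPM, and Gkn2 was 10.7-fold higher, from 0.868 to 9.32 CPM. The ratio of Afp was 0.911 after thinning. Of 14 embryo proper genes 4 were higher and 4 lower (median 0.38, percentile 82.4), among them cardiac Actc1, 8.93-fold higher, and the neural progenitor gene Hes5, 7.41-fold lower. Smooth muscle region 3 held 70.2% of the Actc1 UMIs at E12.5, and without region 12 and the smooth muscle regions Actc1 had a ratio of 3.27.

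Metabolic and proliferation lists had few called members. Of 21 glycogen metabolism genes 2 were higher and 0 lower (median 0.14, percentile 72.3), including Gys2, 3.92-fold higher (2.33-fold with equal weight per spot), and of 32 cell cycle genes 0 were higher and 1 lower (median 0.07, percentile 54.6). The lower gene was Rrm2, a ribonucleotide reductase subunit, 2.20-fold lower, and 1.69-fold with equal weight per spot. Of 34 nutrient transport genes 3 were higher and 2 lower (median 0.21, percentile 98.1), Fabp3, a fatty acid carrier, 2.70-fold higher, from 130 to 350 CPM, and the glucose transporter gene Slc2a3 2.37-fold lower, beside Slc2a1 at a ratio of 1.27. Of 26 hypoxia and glycolysis genes 1 was higher and 0 lower (median 0.15, percentile 84.5). The higher gene was Higd1a, 2.04-fold higher, and 1.91-fold with TMM scaling. Of 36 imprinted genes 3 were higher and 1 lower (median 0.25, percentile 99.1), Zim1 3.47-fold higher and the antisense transcript Kcnq1ot1 2.15-fold lower, while H19 and Gnas had ratios of 1.18 and 1.19. After thinning, Kcnq1ot1 had a ratio of 1.10 and Zim1 one of 5.76, both from few UMIs (222 and 53 at E10.5 before thinning). The percentile of the nutrient transport list was 84.9 after thinning, and that of the imprinted list 63.1 with equal weight per spot.

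Among the remaining lists, 9 of 36 extracellular matrix genes were higher and 1 lower (median 0.30, percentile 99.95). Spp1, osteopontin, was 5.56-fold higher, from 285 to 1583 CPM, and Mmp9, a gelatinase, 11.8-fold lower (8.67 to 16.3), from 24.9 to 2.12 CPM, with a ratio of 0.050 without region 12 and the smooth muscle regions. Of 29 complement and coagulation genes 8 were higher and 1 lower (median 0.28, percentile 99.6), with complement C3 12.9-fold higher, from 37.4 to 483 CPM, and Serpine1 2.23-fold lower, while the summed level of the list was 4651 CPM at E10.5 and 4591 CPM at E12.5. Without region 12, C3 had a ratio of 6.03 and the complement list a percentile of 97.2; with equal weight per spot the percentile was 95.6. Of 26 interferon response genes 1 was higher and 4 lower (median -0.15, percentile 0.32), Ifitm1 2.59-fold higher and Ifit1 3.12-fold lower, and this percentile was 14.3 with equal weight per spot. Ifit1 was 7.49-fold lower after thinning. Of 18 immediate early genes 0 were higher and 0 lower (median 0.13, percentile 72.7). Of the 13 mitochondrially encoded genes 10 were lower and 0 higher (median -1.47, percentile 0), mt-Atp8 4.37-fold lower, from 525 to 120 CPM, and mt-Co3 1.84-fold lower, from 17331 to 9410 CPM.

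Y-linked transcripts were found in the E10.5 section and not in the E12.5 section. Ddx3y (chromosome Y, 1260771 to 1286629) had 251 UMIs at E10.5, Eif2s3y 142, Uty 69 and Kdm5d 36, and each had 0 at E12.5, where a count of 0 allows up to 0.135 CPM. Ddx3y was at least 124-fold lower in the E12.5 section and Kdm5d at least 17.8-fold lower (list median -5.61, percentile 0). Xist, the X-inactivation transcript (chromosome X, 103460366 to 103483254), had a whole-section ratio of 0.962 (0.886 to 1.05). This difference in Y-linked RNA went with every gene group above.

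**Figure D2:**
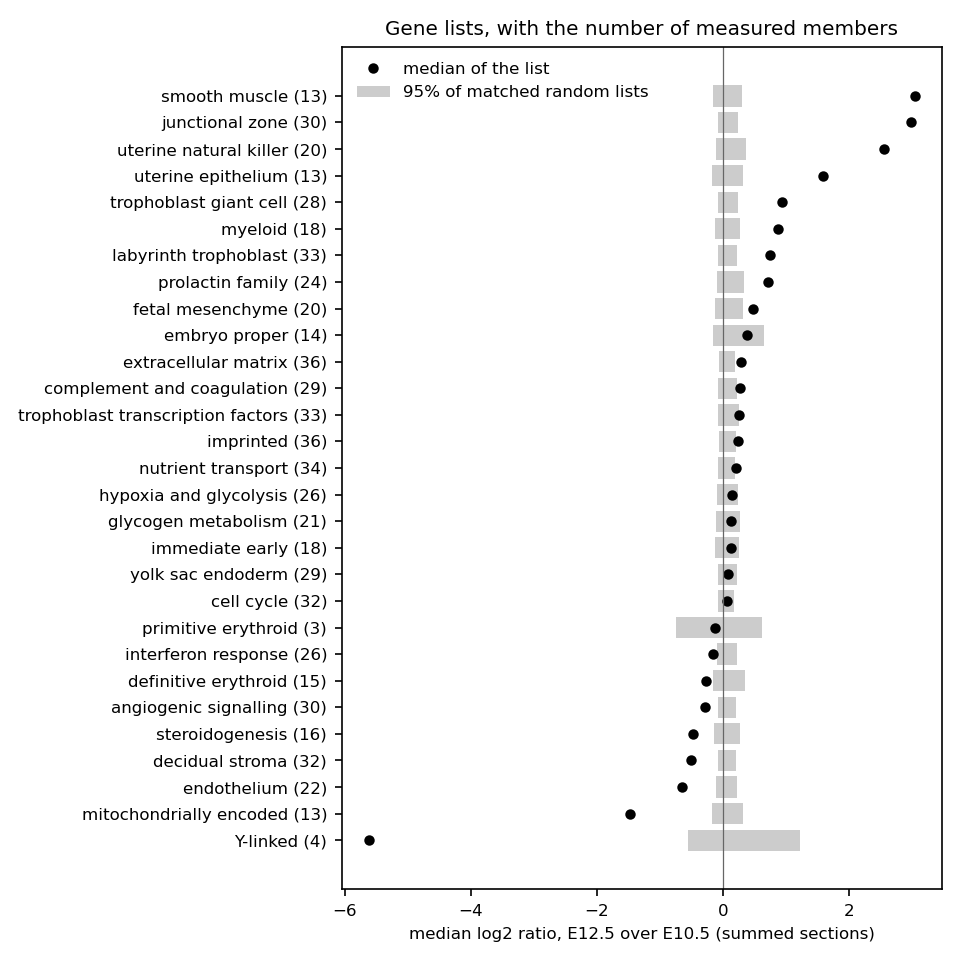
Median log2 ratio of E12.5 to E10.5 CPM over the measured members of each gene list (points, number of members in parentheses), with grey bars for the central 95% of 10000 matched random lists, 1 section per stage. Junctional zone, smooth muscle and uterine natural killer genes had medians of 2.98, 3.05 and 2.55, and the Y-linked list had the lowest median, -5.61.

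Clustering each section on its own gave 8 regions at E10.5 and 12 at E12.5. In the E10.5 section, region 1 (63 spots) was led by Jaml, Mmp9, Akr1c18, Mrgprg and Cyp11b1, and held 60.5% of the Rnase2a UMIs and 49.2% of the Gzmd UMIs. Region 2 (58 spots) was led by Tpbpa, Tpbpb, Prl6a1, Pappa2 and 1600012P17Rik. Region 3 (55 spots), led by Ear1, Chodl, Mgp, Adcy2 and Msc, held 57.5% of the Cxcl14 UMIs and 47.2% of the A2m UMIs, with A2m at 29226 CPM. Region 4 (42 spots) was led by the neural progenitor genes Olig3, Ccnd2, Hes5, Fabp7 and Fzd10, region 5 (37 spots) by Pi16, Cnn1, Myh11, Penk and Col15a1, and region 6 (34 spots) by Vtn, Col9a2, Prodh2, Haao and Foxa2. Region 7 (28 spots) was led by Snap91, Apela, Tulp1, Gjb2 and Ldoc1. Region 8 (25 spots) was led by Prl3d1, Prl7a1, Prl8a9, Serpine1 and Prl4a1.

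In the E12.5 section, region 4 (64 spots) was led by Ceacam12, Prl7a2, Ceacam11, Cts3 and Psg21, and held 62.9% of the Ceacam14 UMIs and 52.8% of the Flt1 UMIs. Region 1 (89 spots) was led by 1600027J07Rik, Hcn4, Mgp, Gzma and Gzmk, and region 7 (55 spots) by 4930486L24Rik, Scgb1a1, S100a8, Mrgprg and Nox4. Region 7 held 34.0% of the Trem2 UMIs and 37.7% of the Gzmd UMIs. Region 3 (71 spots), led by Cnn1, Wfikkn2, Tnni2, Sh3bgr and Pcp4, held 67.6% of the Acta2 UMIs. Regions 5 (63 spots) and 8 (54 spots) were led by Apela, Lonrf3, Dcaf12l1, Myl4 and Fabp3, and by C1ql2, Lrrn4, Syna, Snap91 and Tfrc. Yolk sac endoderm was the class of region 2 (73 spots; Klb, Pga5, Gkn2, Igfals, Slc2a2) and of region 9 (54 spots; H2-Q10, Mfsd4b5, Ahsg, Angptl6, F2). Region 6 (56 spots) was led by Prr9, Sprr2h, Guca2a, Rimklb and Tchh, region 10 (53 spots) by Prl7a1, Slfn4, Ifi44, Rasgrp3 and Prl3d1, and region 11 (52 spots) by Ear1, Ear2, Cxcl14, Aqp1 and Gm50353. Region 12 (30 spots) was led by Klk1, Cuzd1, Prap1, Lrg1 and Csf1, and held 63.3% of the Prap1 UMIs, 62.9% of the Guca2b UMIs and 56.1% of the Akr1b7 UMIs.

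The authors' deposited tables gave 6 clusters at E10.5, with 11417 entries of cluster marker genes, and 9 clusters at E12.5, with 15051. In the authors' deposited table for E10.5 the gene with the highest average log2 fold change was Akr1c18 (2.71) in cluster 0, Fabp3 (2.60) in cluster 1, Tpbpa (3.87) in cluster 2, Mgp (2.88) in cluster 3, Penk (3.27) in cluster 4 and Spp2 (2.34) in cluster 5. In the authors' deposited table for E12.5 it was Fabp3 (2.90) in cluster 0, Mgp (3.04) in cluster 1, Prl8a2 (2.68) in cluster 2, Afp (3.74) in cluster 3, Prl7a2 (3.73) in cluster 4, Cnn1 (4.67) in cluster 5, Cxcl14 (3.30) in cluster 6, 4930486L24Rik (3.92) in cluster 7 and Prap1 (4.66) in cluster 8. Of the 50 leading genes of cluster 8 in the authors' deposited table, 50 were among the 200 leading genes of region 12, and for cluster 5 the overlap with E12.5 region 3 was 49. The lowest best overlap was 34 of 50, for cluster 1 of the authors' deposited table for E10.5.

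**Figure D3:**
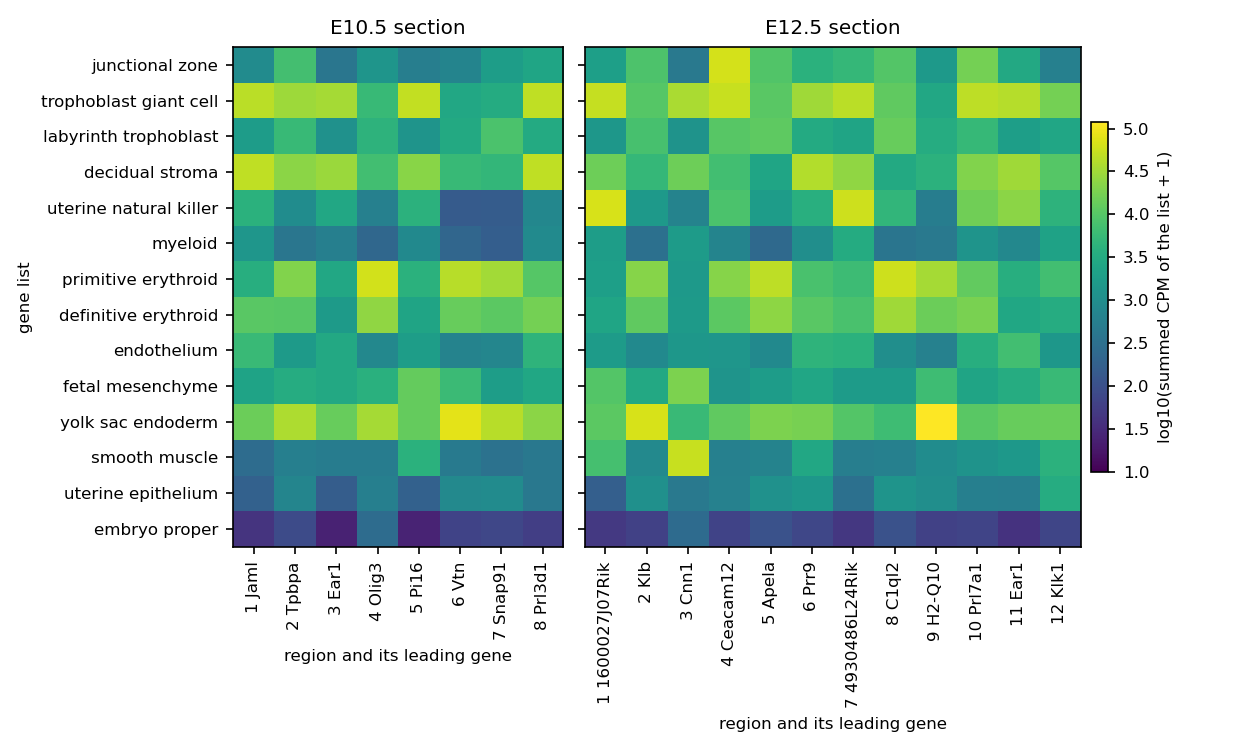
Summed CPM of each cell type list in each region of the 2 sections, as colours on a log scale, with 8 regions at E10.5 and 12 at E12.5. Junctional zone genes summed to 64450 CPM in E12.5 region 4.

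The labyrinth, the layer of exchange between maternal and fetal blood, could be compared within its regions. Region 7 made up 8.19% of spots at E10.5 (5.51 to 11.6), and regions 5 and 8 together 16.4% at E12.5 (13.7 to 19.3). Intervals of shares, here and below, are binomial and treat the spots of a section as independent draws. They do not cover the plane of cutting or the clustering setting, so they do not show a difference of stage. At resolution 0.4 the shares were 21.1% at E10.5 and 19.3% at E12.5, and with both sections clustered together the E12.5 share was 9.80%. Most measured junctional zone genes were higher and most yolk sac genes lower in the E12.5 labyrinth regions 5 and 8 than in E10.5 region 7. Tpbpa was at 67.8 CPM in region 7 and 4301 CPM in regions 5 and 8, 63.5-fold higher (51.7 to 78.9). Tpbpb, Prl7a2, Ceacam11 and Ceacam13 had 0 UMIs in region 7 and were at least 135-fold, 92.1-fold, 73.9-fold and 63.5-fold higher. Car7, a carbonic anhydrase gene, was 19.3-fold lower (11.9 to 32.9), and the lipoprotein gene Apob was 6.09-fold lower.

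In these regions, 10796 genes were measured, 648 of them higher and 493 lower. Of 24 junctional zone genes 19 were higher and 0 lower (median 3.52), and of 10 uterine natural killer genes 10 were higher (median 4.38), with Gzmd 32.3-fold higher. At E12.5, Gzmd had UMIs in 96.4% of all spots and Tpbpa in 99.3%. A spot can hold several cell types, so these ratios do not show a change in labyrinth cells. Of 29 yolk sac endoderm genes 22 were lower and 1 higher (median -1.78). The retinol carrier gene Rbp4 was 6.47-fold lower, Cubn, the cubilin receptor gene, 6.22-fold, and Afp 3.42-fold, from 18666 to 5453 CPM. Labyrinth genes, which define the class, had 7 of 31 higher and 1 lower (median 0.57). Of 34 nutrient transport genes 0 were higher and 4 lower, with Slc2a3 5.83-fold lower and Fabp3 at a ratio of 1.96, while the median of the list was 0.29, above its matched random lists (percentile 99.7). Of 19 interferon response genes 6 were higher and 0 lower (median 0.81), and of 13 mitochondrially encoded genes 11 were lower (median -1.92). Xist was at 2.23 CPM in region 7 and 41.3 CPM in regions 5 and 8, 18.5-fold higher (6.19 to 90.6). Of 564 measured genes that were higher in the whole E12.5 section, 232 were also higher here and 2 lower, and of 211 that were lower, 63 were also lower and 6 higher. Yolk sac genes summed to 43019 CPM in E10.5 region 7 and to 18792 and 6576 CPM in E12.5 regions 5 and 8, so the class held unequal amounts of yolk sac transcripts.

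In the smooth muscle regions, 16 of 29 decidual stroma genes and 10 of 12 uterine natural killer genes were lower, and 15 of 29 cell cycle genes higher, at E12.5 (region 3) than at E10.5 (region 5). E10.5 region 5 made up 10.8% of spots (7.73 to 14.6) and E12.5 region 3 9.94% (7.85 to 12.4). The E12.5 share was 3.08% at resolution 1.2, and 3.22% with variable genes without haemoglobin, mitochondrial and ribosomal protein genes. A2m was at 18998 CPM in region 5 and 345 CPM in region 3, 55.0-fold lower (50.7 to 59.8), and Gzma was 90.2-fold lower (41.1 to 247). Hcn4, a pacemaker channel gene, was at 108 CPM in region 5 and had 0 UMIs in region 3, at least 61.7-fold lower. Outside the class, in E12.5 region 1, Hcn4 was at 105 CPM, Gzma at 2125 CPM and A2m at 5685 CPM. Of the 30 leading genes of E10.5 region 5, 9 also led E12.5 region 3 and 4 led E12.5 region 1, among them Penk and Stc2. Tnni2, a skeletal muscle troponin that leads region 3, was 397-fold higher (110 to 3280, with 2 UMIs at E10.5), and the immunoglobulin gene Igha, with 0 UMIs in region 5, was at least 184-fold higher.

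Of 9850 genes measured in these regions, 1422 were higher and 997 lower. At resolution 1.2 the balance turned, with 1042 higher and 1247 lower. The 12 measured smooth muscle genes, which define the class, were higher (median 3.65), with Actg2 19-fold (17.8 to 20.2) and Acta2 17.9-fold higher. The cell cycle genes, of which 2 were lower, had a median of 1.13, with Ccnd1, cyclin D1, 6.54-fold higher and Rrm2 17.6-fold lower, and their summed level was 2425 CPM in region 5 and 1254 CPM in region 3. Of 36 extracellular matrix genes 13 were higher, 1 lower and 22 neither (median 0.55, with a bootstrap interval over the members of -0.04 to 1.02). The decidual stroma list, with 4 genes higher, had a median of -1.04, and the natural killer list, with 1 gene higher, a median of -3.60. Of 17 giant cell genes 12 were lower and 0 higher (median -1.99). Of 16 myeloid genes 8 were higher and 1 lower (median 1.01). Of 13 mitochondrially encoded genes 9 were lower (median -1.18). Smooth muscle genes summed to 3974 CPM in E10.5 region 5 and 55069 CPM in E12.5 region 3, and decidual stroma genes to 22124 and 15212 CPM. With both sections clustered together, no E10.5 region belonged to the class. It thus paired unlike mixtures of tissue, and these ratios and counts do not show a change in smooth muscle cells.

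**Figure D4:**
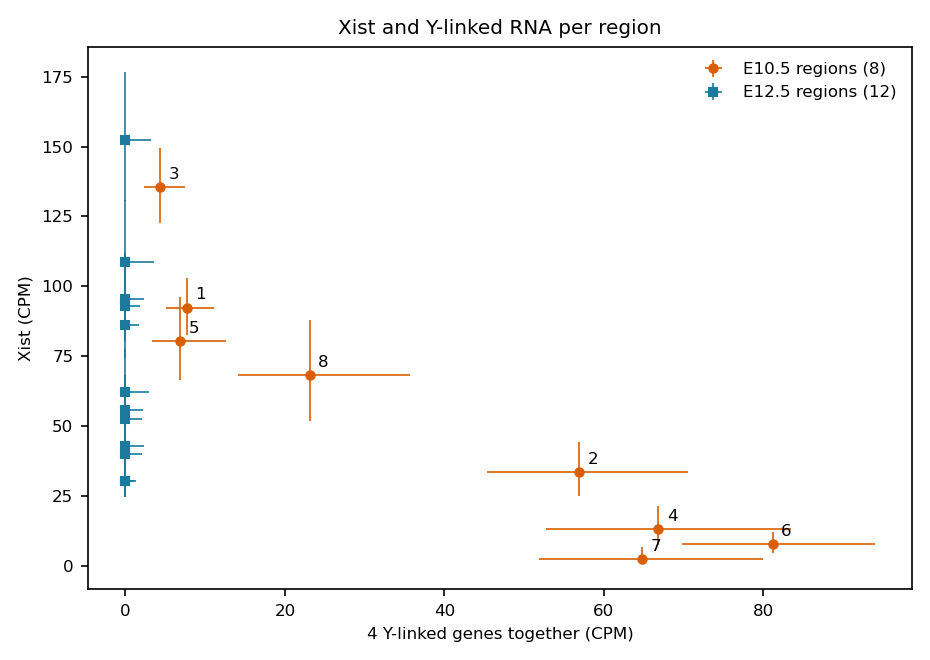
Xist CPM (vertical axis) against the CPM of the 4 Y-linked genes together (horizontal axis), each point a region of the E10.5 or the E12.5 section with 95% counting intervals. At E10.5, Y-linked RNA ranged from 4.4 CPM in region 3 to 81.2 CPM in region 6, and at E12.5 it was 0 in all 12 regions, where Xist ranged from 30.2 to 152 CPM.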

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

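The following gene lists had medians of opposite sign in the labyrinth class (E10.5 region 7 against E12.5 regions 5 and 8) and in the smooth muscle class (E10.5 region 5 against E12.5 region 3), each outside the central 95% of matched random lists. They were picked out because the sections differed in opposite ways in the 2 classes. The difference between the classes was not tested, and no explanation was tested. As given above, the paired regions held unequal amounts of yolk sac transcripts in the labyrinth class and of smooth muscle transcripts in the smooth muscle class. The opposite signs therefore do not show opposite changes within a cell type. All median log2 ratios are E12.5 over E10.5. The bootstrap interval over the members included 0 for the junctional zone, labyrinth trophoblast and transcription factor lists in the smooth muscle class, and for the primitive erythroid list in the labyrinth class.

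Junctional zone genes had a median log2 ratio of 3.52 in the labyrinth regions, with 19 of 24 higher, and -0.69 in the smooth muscle regions, with 5 of 12 lower. Trophoblast giant cell genes had 0.97, with 11 of 24 higher, against -1.99, with 12 of 17 lower. For the prolactin family the medians were 3.32 and -2.02, with 9 of 15 higher in the labyrinth and 9 of 12 lower in the smooth muscle regions. Labyrinth trophoblast genes had 0.57 and -0.31. Trophoblast transcription factors had 0.44 and -0.57.

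Uterine natural killer genes had a median of 4.38 in the labyrinth regions, with 10 of 10 higher, and -3.60 in the smooth muscle regions, with 10 of 12 lower. The 3 primitive erythroid globins had medians of 0.55 and -1.76. Cell cycle genes went the other way, with -0.34 in the labyrinth regions, where 0 of 31 were called in either direction, and 1.13 in the smooth muscle regions, where 15 of 29 were higher while their summed level was 2425 CPM at E10.5 and 1254 CPM at E12.5.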

How the results depend on the processing

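The settings without E12.5 region 12, alone or with the smooth muscle regions, were chosen after the results were seen; the others were set before the data were examined. The counts of 1479 genes higher and 569 lower stayed within 1.5 times under the scalings of edgeR and DESeq2, totals without haemoglobin and mitochondrial genes, equal weight per spot, a minimum of 1000 UMIs per spot, no minimum count, and both added settings. The share of calls that were higher ranged from 64.6% to 72.2%. Equal weight per spot kept 1220 of the higher and 408 of the lower genes, and leaving out region 12 kept 1279 and 531. Thinning to 2000 UMIs gave 509 higher and 279 lower among only 9222 genes with enough UMIs, 311 and 131 of them shared. A minimum of 100 UMIs gave 858 and 359 among 12243 genes, and a limit of 1.5-fold gave 2368 and 1190, both by construction. The ratio of Kcnq1ot1 was 0.465 as reported and 1.10 after thinning, and the cause was not tested. Kcnq1ot1 had 222 UMIs at E10.5 and 153 at E12.5 before thinning, so its thinned ratio rests on few UMIs. From 11 to 14 lists lay above and 7 to 9 below their matched random lists. Of 269 list medians under the alternatives, 244 stayed within the bootstrap interval over the list's members, 25 moved and 0 of those outside the matched range reversed. Of the finite ratios of named genes, 515 stayed within their counting interval, 483 moved and, of those called, 1 reversed. Percentiles that came inside the central 95% were those of nutrient transport (84.9 thinned, 96.8 at a minimum of 100 UMIs), imprinted (63.1 with equal weight, 71.9 thinned), interferon response (14.3 and 4.86), complement and coagulation (95.6 and 88.1, and 97.2 without region 12), trophoblast transcription factors (87.9 and 58.6) and definitive erythroid genes (2.52 without region 12 and the smooth muscle regions). The labyrinth share of spots was 21.1% at E10.5 and 19.3% at E12.5 at resolution 0.4, and at E12.5 13.7% at resolution 1.2 and 9.80% with both sections clustered together. The smooth muscle share at E12.5 was 3.08% at resolution 1.2 and 3.22% with variable genes without haemoglobin, mitochondrial and ribosomal protein genes. The cause of these moves was not tested. With both sections clustered together, no E10.5 region belonged to either class, so that setting gave no comparison within regions. Counts within the regions stayed within 1.5 times at resolution 1.2 (labyrinth 621 higher and 481 lower, smooth muscle 1042 and 1247, where lower calls outnumbered higher ones, against 1422 and 997 as reported) and without haemoglobin and mitochondrial genes (584 and 527, 1351 and 1050). Depth set the floors of 0.200 CPM at E10.5 and 0.135 CPM at E12.5 that a count of 0 allows. The chosen thinning target left 684000 and 1424000 UMIs and left out 2 spots at E12.5. No paired analysis was possible because there was 1 section per stage.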

Other observations

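The 3 tests of the Y-linked pattern, and all tests that leave out E12.5 region 12, were chosen after the whole-section results were seen, as were the genes compared by region here. Several genes with lower whole-section levels at E12.5 were still abundant there in single regions. A2m reached 29226 CPM in E10.5 region 3 and 22771 CPM in E12.5 region 11, both led by Ear1, against a minimum of 318 CPM among the E12.5 regions. Cxcl14, a chemokine gene, reached 4001 CPM in the former and 2549 CPM in the latter. The decidual Prl8a2 reached 33393 CPM in E10.5 region 8, the region led by Prl3d1, and 15443 CPM in E12.5 region 6, led by Prr9. Tdo2 reached 915 CPM in E10.5 region 3 and 144 CPM in E12.5 region 11.

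The granzyme gene Gzmd, Spp1 and Cyp11a1 shared a region of highest level in each section. At E10.5, Gzmd (1016 CPM), Spp1 (517 CPM) and Cyp11a1 (883 CPM) were highest in region 1, as were Gzmf (865 CPM), Akr1c18 and Mmp9. Ncr1, with 21 UMIs in the section, was highest in region 5, Cyp17a1 in region 2 and Star in region 8. Klrk1 had only 4 UMIs at E10.5, too few to rank the regions. At E12.5, Gzmd (15851 CPM), Spp1 (5465 CPM) and Cyp11a1 (474 CPM) were highest in region 7, led by 4930486L24Rik. Gzmf, Klrk1 and Ncr1 were highest in E12.5 region 1, Gzmf at 15907 CPM, Akr1c18 in region 12, Cyp17a1 in region 4 and Star in region 10. Flt1, whose product binds vascular endothelial growth factor, was highest in regions with spongiotrophoblast genes, at 65.1 CPM in E10.5 region 2 and 967 CPM in E12.5 region 4.

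Y-linked genes had UMIs in every region of the E10.5 section and 0 in the E12.5 section. At the E10.5 level, 738 Y-linked UMIs would have been found at the depth of the E12.5 section, and 218 in its labyrinth regions alone at the level of E10.5 region 7, which held 87; both values argue against too little depth and against too little fetal tissue. Xist was 18.5-fold higher in the E12.5 labyrinth regions (6.19 to 90.6, 3 UMIs against 139). The absence of Y-linked UMIs there, already seen, made a higher Xist likely, so the Xist ratio adds little. Uterine natural killer genes were higher in the same comparison (144 to 3173 CPM), so maternal RNA can also raise Xist. A candidate explanation is that the 2 sections came from conceptuses of different sex, male at E10.5 and female at E12.5, with Xist of maternal tissue in both. Sex would then be confounded with stage in fetal regions; the labels used here give no sex.

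Guca2b, Akr1b7 and Prap1 had more than 20-fold higher levels at E12.5 and were concentrated in the 30 spots of E12.5 region 12. Without those spots their median ratio was 9.19, from 8.32 for Prap1 to 12.4 for Akr1b7, as a difference that reached beyond region 12 would give. Regions 3 and 6 held 67.2% to 69.5% of the remaining UMIs. Without these regions as well the median ratio was 3.57, from 3.0 for Prap1 to 4.79 for Akr1b7. These are ranges over the genes and not intervals of counting error. The median of the uterine epithelium list was 3.01-fold over 13 genes, and 2.40-fold without region 12. A prediction was written before the ratios without region 12 were computed. It held that a tissue cut by the E12.5 section and hardly by the E10.5 section needs a median below 2 without region 12. It also needed a uterine epithelium median of at least 2-fold, which was met, although that list does not stand for uterine epithelium alone. The bound of 2 was not met at 9.19, nor at 3.57 without regions 3 and 6 as well. That bound assumed a tissue confined to the spots left out, a limit seen only after the result. For these genes, the plane of cutting and a difference of stage cannot be told apart with 1 section per stage. A wider set of 19 genes with their highest level in region 12 had a median of 5.22, and 3.85 without it.

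Mitochondrially encoded genes had a median log2 ratio of -1.47. The median was -1.92 in the labyrinth class and -1.18 in the smooth muscle class. Both classes held unequal smooth muscle or yolk sac transcripts in the 2 sections, so these medians cannot decide on the mix of regions. The mitochondrial share was 4.35% to 11.5% among E10.5 regions and 1.98% to 5.37% among E12.5 regions. No mix of the E12.5 regions reaches the 7.69% of the E10.5 section, which argues against a different mix of the same regions. Among spots with 20000 to 40000 UMIs (135 at E10.5, 398 at E12.5) the median log2 ratio was -1.55, which argues against UMIs per spot. With TMM scaling it was -1.56, which argues against a few abundant genes. What stays open is unlike tissue in the 2 sections and a difference of stage, which were not tested. Differences in freezing, tissue handling or RNA quality between the sections stay open too, as no measurement of them was used here.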
